A study of Homo sapiens with 48 samples.

How the data were processed

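Gene counts deposited by the authors were used without change. Per the submitters' processing notes, reads were counted with HTSeq on the human genome hg19, while the aligner and the versions of these tools were not given in the sources used here. The labels name 2 replicates per group and describe cells treated in duplicates in advanced RPMI with 5% FBS, total RNA prepared with Qiagen AllPrep and standard Illumina libraries. They do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The chi-square per degree of freedom ran from 2.62 to 9.04 between replicates and was at least 2.62 over all 1128 pairs of libraries, where repeated reads of a library would give a value near 1. The table held 25066 genes. Of these, 3449 had no gene ID and held 0.81% of the reads, and they were kept for filtering and scaling. The 27 symbols turned into dates were renamed by Entrez ID.

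Groups, comparisons, gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, from the sample labels alone. Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3), and 13881 genes passed filterByExpr by group. A negative binomial model with 1 mean for each of the 24 groups was fitted and tested with edgeR's quasi-likelihood F test on 24 residual degrees of freedom. Genes were called at an adjusted p under 0.05, adjusted by the Benjamini-Hochberg method within each comparison. The common dispersion was 0.00539, a coefficient of variation of 7.3% between libraries of a group. There were 18 comparisons of a compound with DMSO in the same line at the same time, 9 of the compound effect between lines (TMD8 minus HBL1), 6 of the effect at 24 h minus 3 h, 6 of compounds directly at 24 h, and DMSO at 24 h against 3 h in each line. Log2 CPM values used a prior count of 2, and CPM values are means and SD of the libraries of a group. Where a group had 0 reads, a bound with a floor of 3 reads over the group is given, and where it had 1 to 3 reads, a ratio with an exact 95% interval, each of which covers counting error alone.

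For 22 gene lists, camera in limma 3.58.1 was run on voom weights with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 396 tests of list and comparison with DMSO. The lists were NF-kB targets (24 of 24 members tested), immediate early and ERK feedback genes (19 of 22, without DUSP6, SPRY2 and SPRY4), FOXO targets (17 of 22, without IL7R, INSR, SESN3, RAG1 and RAG2), MYC targets and ribosome biogenesis (27 of 27), ER chaperones and ERAD genes targeted by XBP1 and ATF6 (27 of 27), ATF4 and CHOP targets (31 of 32, without NUPR1), oligosaccharyltransferase and N-glycan precursor genes (37 of 37), cholesterol synthesis (24 of 25), glycolysis (20 of 20), G1/S and DNA replication (21 of 21), G2/M (20 of 20), STAT3 and cytokine response (17 of 17), interferon-stimulated genes (22 of 24, without HERC5 and RSAD2), B cell identity and receptor pathway (26 of 26), plasma cell differentiation (12 of 12), germinal centre (11 of 12, without MME), MHC class II (12 of 12), p53 targets (15 of 16, without GDF15), lysosome and autophagy (21 of 22, without CTSL1), T and NK cells (3 of 11), myeloid cells (2 of 11) and stromal or epithelial cells (8 of 12). The lists were written from memory of the literature and were not checked against a database. Within the 396 tests 186 passed with the preset correlation, 70 of them also with a correlation estimated from the data, and 162 passed with fry. In 61 results the median, the mean and the test differed in sign, and 2 of these were called. Counts adjusted over the list alone used the same gene p-values with the adjustment restricted to its members.

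Named genes followed a rule: per compound the 8 higher and 8 lower genes at 24 h, and 4 and 4 at 3 h, with the largest change in the line that changed less, among genes called in both lines with a mean log2 CPM of at least 1, then up to 3 called members per list, 15 genes fixed by name, 3 genes per direction with the smallest adjusted p for the line difference, and 4 per direction for each direct comparison. The rule gave 150 genes. The text prints those that stood highest, with preference for calls that did not depend on a single library, a preference set after the values were seen. Symbols are those of the table, with newer names in brackets. Reads of near-identical genes, such as CCL3 and CCL3L1, CCL4 and its copies, and MHC genes, may have been shared or dropped by the counting, which was not examined here. Genome positions were not analysed.

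Results were recomputed with RLE size factors, no filter on low counts, a stricter filter (CPM of at least 1 in 2 libraries and a mean log2 CPM of at least 1), DESeq2 1.42.0, a separate fit of each line, a replicate block, each library left out in turn, and for lists the estimated correlation and fry. When a library was left out, its group kept a lone sample, which was assumed to vary like the other groups. Added after seeing the data were a block for replicate number within each line and time, list tests without each library, list tests for the line, time, direct and DMSO comparisons, and 12 direct comparisons at 3 and 6 h. Overlap between compounds was set against the number expected for independent calls and against 20 simulations of unchanged groups sharing DMSO libraries.

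As a test of the method, counts were simulated for NGI-1 against DMSO in TMD8 at 24 h with the means and dispersions of the data, 13656 genes, 200 changed genes and a list of 25 further genes raised 1.3-fold. At a true change of 1.5-fold 60 of 100 genes were found, at 2-fold 44 of 50 and at 4-fold 49 of 50. Of 167 calls 8 were genes of the list and 6 were false. These rates hold for that comparison only. Each compound was given at 1 dose, so effects on the intended target and on other targets cannot be told apart, and genes in the counts table alone do not show protein or glycosylation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.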

Results

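RNA-seq counts were examined for 48 libraries of the Cas9-engineered activated B cell-like diffuse large B cell lymphoma lines TMD8 and HBL1. Cells had received vehicle (DMSO), the oligosaccharyltransferase inhibitor NGI-1 (5 µM), the BTK inhibitor acalabrutinib (50 nM) or the PI3K inhibitor copanlisib (20 nM) for 3, 6 or 24 h, with 2 libraries in each of 24 groups. The libraries held 7165377 to 11999050 counted reads. Of 25066 genes, 13881 had enough reads to be tested. Every library correlated best with a library of the same line and time (48 of 48). For 22 of them this was the other library of the same group. For the other 26 it was a library of the same replicate number, which the main fit did not model. Among the genes named by the rule set beforehand, 1111 changes against DMSO passed the adjusted p threshold. In 1111 of these both treated libraries lay beyond both DMSO libraries. The same libraries made the calls, so this is no separate check. Values are log2 fold changes ± SE against DMSO at the same time in the same line, from 2 libraries per group, unless other units are given.

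Compared with DMSO, 3 h after NGI-1 the expression of 79 genes was higher and 23 lower in TMD8. In HBL1, 49 were higher and 0 lower. There DESeq2 called 59 higher and 0 lower, and without the filter 97 were higher and 4 lower. By edgeR 744 genes had an unadjusted p under 0.05 in either direction. With a replicate block 116 were higher and 7 lower there, and with a block within each line and time 226 and 81. After 6 h, 314 genes were higher and 276 lower in TMD8, and 150 higher and 10 lower in HBL1. By 24 h, NGI-1 had raised 2166 and lowered 2057 genes in TMD8 (460 and 243 of them at least 2-fold). It had raised 1093 and lowered 1577 in HBL1 (228 and 92 at least 2-fold). The early counts fell when certain libraries were left out, although a group of 1 sample has less power by itself. The 102 genes of TMD8 at 3 h became 47 without DMSO replicate 1, 63 without DMSO replicate 2 and 42 without NGI-1 replicate 1. The 590 at 6 h became 193, 260 and 247 without DMSO replicate 1, NGI-1 replicate 1 and NGI-1 replicate 2. In HBL1 the 49 at 3 h became 7 without DMSO replicate 1 and 24 without NGI-1 replicate 1. The 160 at 6 h became 47 without DMSO replicate 1 and 43 without NGI-1 replicate 2. The 2670 at 24 h in HBL1 became 1345, 1647 and 1649 without DMSO replicate 1, NGI-1 replicate 1 and NGI-1 replicate 2. In TMD8 the 4223 stayed between 2992 and 3149.

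**Figure D1:**
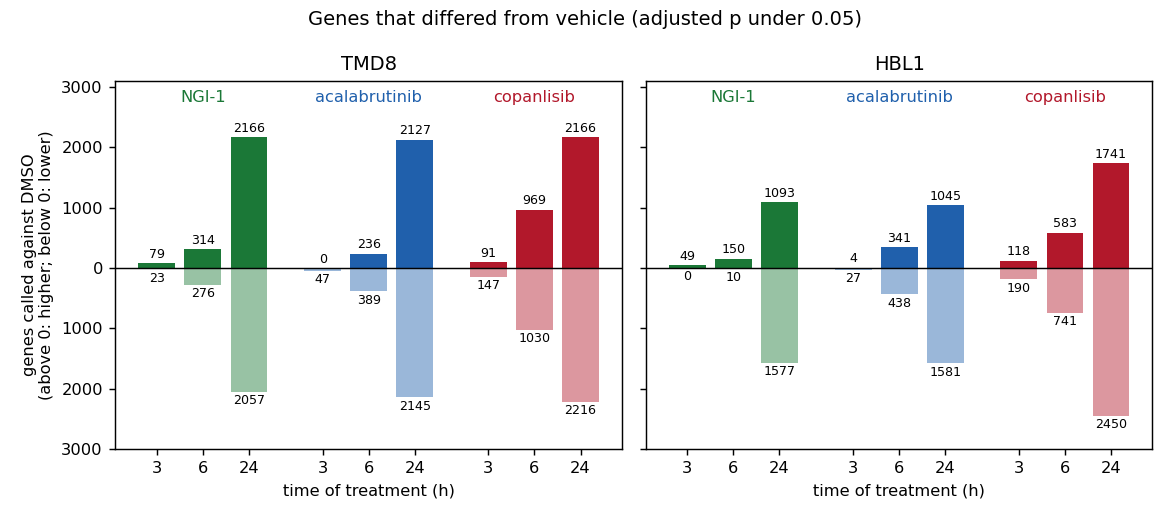
Number of genes called higher (bars above 0) and lower (bars below 0) against DMSO for each compound, time and line, 2 libraries per group. NGI-1 changed 102 genes in TMD8 at 3 h and 4223 at 24 h.

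Chaperone genes of the endoplasmic reticulum rose within 3 h of NGI-1. HSPA5, which encodes the chaperone BiP, rose 4.86-fold at 3 h in TMD8, from 818 ± 107 to 3970 ± 262 CPM (reads scaled for library size, mean ± SD, n = 2 libraries). The log2 change was 2.28 ± 0.16 (adjusted p = 7.1e-10). In HBL1 it rose 2.71-fold at 3 h, from 1480 ± 107 to 4010 ± 410 CPM (1.44, adjusted p = 1e-05). At 24 h HSPA5 was still raised by 1.41 in TMD8 and 0.96 in HBL1. SDF2L1, a partner of BiP, rose 4.19-fold in TMD8 (2.07 ± 0.16, adjusted p = 3.4e-12) and 2.55-fold in HBL1 (1.35 ± 0.15, adjusted p = 1.3e-07) at 3 h. It remained higher at 24 h (1.53 and 0.79 ± 0.15). DERL3, a component of endoplasmic reticulum-associated degradation, rose by 1.89 ± 0.27 at 3 h and 1.91 ± 0.25 at 24 h in TMD8. In HBL1 it rose by 1.55 ± 0.24 at 6 h and 1.16 ± 0.24 at 24 h. Of the 27 chaperone and degradation genes targeted by XBP1 and ATF6, 20 were higher and 0 lower in TMD8 at 3 h (25 higher when adjusted over the list alone). Their median was 0.94 (camera adjusted p = 2.4e-100, 0.00018 with an estimated correlation). In HBL1, 17 were higher and 0 lower at 3 h (24 over the list alone), with a median of 0.66 (2e-83, 0.00035 with an estimated correlation). At 6 h the medians were 1.27 in TMD8 (23 higher, 0 lower, 26 higher over the list alone, 2.6e-76, 0.00048 with an estimated correlation). HBL1 reached 0.95 (21 higher, 0 lower, 25 over the list alone, 1.6e-80, 0.00043 with an estimated correlation). The list was still raised at 24 h, by a median of 0.98 in TMD8 (24 higher, 0 lower, 24 over the list alone, camera adjusted p = 1.2e-19, lost at adjusted p = 0.073 with an estimated correlation). In HBL1 the median was 0.56 (18 higher, 0 lower, 19 over the list alone, 4.6e-14, lost at adjusted p = 0.14).

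XBP1, the transcription factor gene whose transcript IRE1 splices, rose 3.31-fold in TMD8 at 3 h (1.73 ± 0.13, adjusted p = 4.2e-11) and stayed higher at 24 h (1.46 ± 0.14). In HBL1 it rose by 0.56 ± 0.12 at 24 h (adjusted p = 0.00083). The NGI-1 effect on XBP1 differed between the lines by 1.19 ± 0.18 at 3 h (adjusted p = 0.0016, 0.051 without the TMD8 DMSO replicate 2) and 0.89 ± 0.18 at 24 h (adjusted p = 0.0025). At 6 h the call on a difference of 0.76 ± 0.18 depended on the method (adjusted p = 0.18, 0.2 with RLE size factors, 0.018 by DESeq2, 4.1e-05 without the filter, 0.0034 with a replicate block). DDIT3, which encodes the stress factor CHOP, rose 4.55-fold in TMD8 at 3 h (2.19 ± 0.32, adjusted p = 0.00015). In HBL1 DDIT3 was not called (1.26 ± 0.32, adjusted p = 0.097). Of 31 tested ATF4 and CHOP targets, 8 were higher and 0 lower in TMD8 at 3 h (22 higher over the list alone). Their median was 0.56 (camera adjusted p = 6.8e-40, 0.0098 with an estimated correlation). At 6 h 15 were higher and 0 lower (20 over the list alone, median 0.47, 1.2e-22), a call lost with an estimated correlation (adjusted p = 0.054). In HBL1 at 3 h 0 were higher and 0 lower (1 higher over the list alone, median 0.12, 0.00012). That call was lost at adjusted p = 0.53 with an estimated correlation, and without DMSO replicate 1 (0.77) or NGI-1 replicate 2 (0.93). At 6 h 1 was higher and 0 lower (3 over the list alone, median 0.34, 1.6e-09, lost at adjusted p = 0.27 with an estimated correlation). In HBL1 at 24 h 1 was higher and 10 lower (3 and 15 over the list alone). The median there was -0.41 (camera adjusted p = 0.00018, lost at adjusted p = 0.54 with an estimated correlation). In TMD8 at 24 h 4 were higher and 5 lower. The median was -0.09 while the mean was 0.02, and the test, directed downward, gave adjusted p = 0.57. Acalabrutinib also lowered the list at 24 h, in TMD8 (1 higher, 18 lower, median -0.58, 1.9e-05, lost at adjusted p = 0.48 with an estimated correlation) and HBL1 (1 higher, 14 lower, 1 and 20 over the list alone, median -0.56, 6.1e-07, lost at adjusted p = 0.39). So did copanlisib, in TMD8 (1 higher, 17 lower, median -0.52, 0.00025, lost at adjusted p = 0.55) and HBL1 (1 higher, 20 lower, 1 and 22 over the list alone, median -0.57, 3.6e-07, lost at adjusted p = 0.38).

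The glycosylation machinery itself rose modestly with NGI-1. MAGT1, a subunit of the STT3B-containing oligosaccharyltransferase, rose at 6 h by 0.88 ± 0.09 in TMD8 (adjusted p = 2.3e-09) and 0.71 ± 0.09 in HBL1 (adjusted p = 1.5e-06). STT3B, a catalytic subunit, rose in TMD8 by 0.6 ± 0.08 at 6 h (adjusted p = 8e-07) and 0.59 ± 0.08 at 24 h (adjusted p = 1.5e-07). STT3A rose in TMD8 by 0.51 ± 0.1 at 6 h (adjusted p = 0.00039). In HBL1, STT3B rose by 0.35 ± 0.08 at 6 h (adjusted p = 0.0099), a call lost without DMSO replicate 1 (0.13), DMSO replicate 2 (0.097), NGI-1 replicate 1 (0.06) or NGI-1 replicate 2 (0.21). OSTC, another subunit of the complex, rose by 0.65 ± 0.11 at 6 h in TMD8 (adjusted p = 6.7e-05). Of 37 oligosaccharyltransferase and N-glycan precursor genes, 9 were higher and 0 lower in TMD8 at 6 h (10 over the list alone, median 0.18, camera adjusted p = 3.4e-10, 0.0024 with an estimated correlation). In HBL1, 7 were higher and 0 lower at 6 h (12 over the list alone, median 0.22, 4.5e-14, 0.00046 with an estimated correlation). The list was already higher at 3 h, with a median of 0.1 in TMD8 (2 higher, 0 lower, 7 over the list alone, 2.3e-06, 0.019 with an estimated correlation). In HBL1 it was 0.15 (2 higher, 0 lower, 5 over the list alone, 3.8e-07, 0.012 with an estimated correlation). At 24 h in TMD8, 12 were higher and 0 lower (13 over the list alone, median 0.22, 0.0048), a call lost with an estimated correlation (adjusted p = 0.16). In HBL1 the list was not called at 24 h (4 higher, 1 lower, 3 and 1 over the list alone, median 0.13, adjusted p = 0.12).

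**Figure D2:**
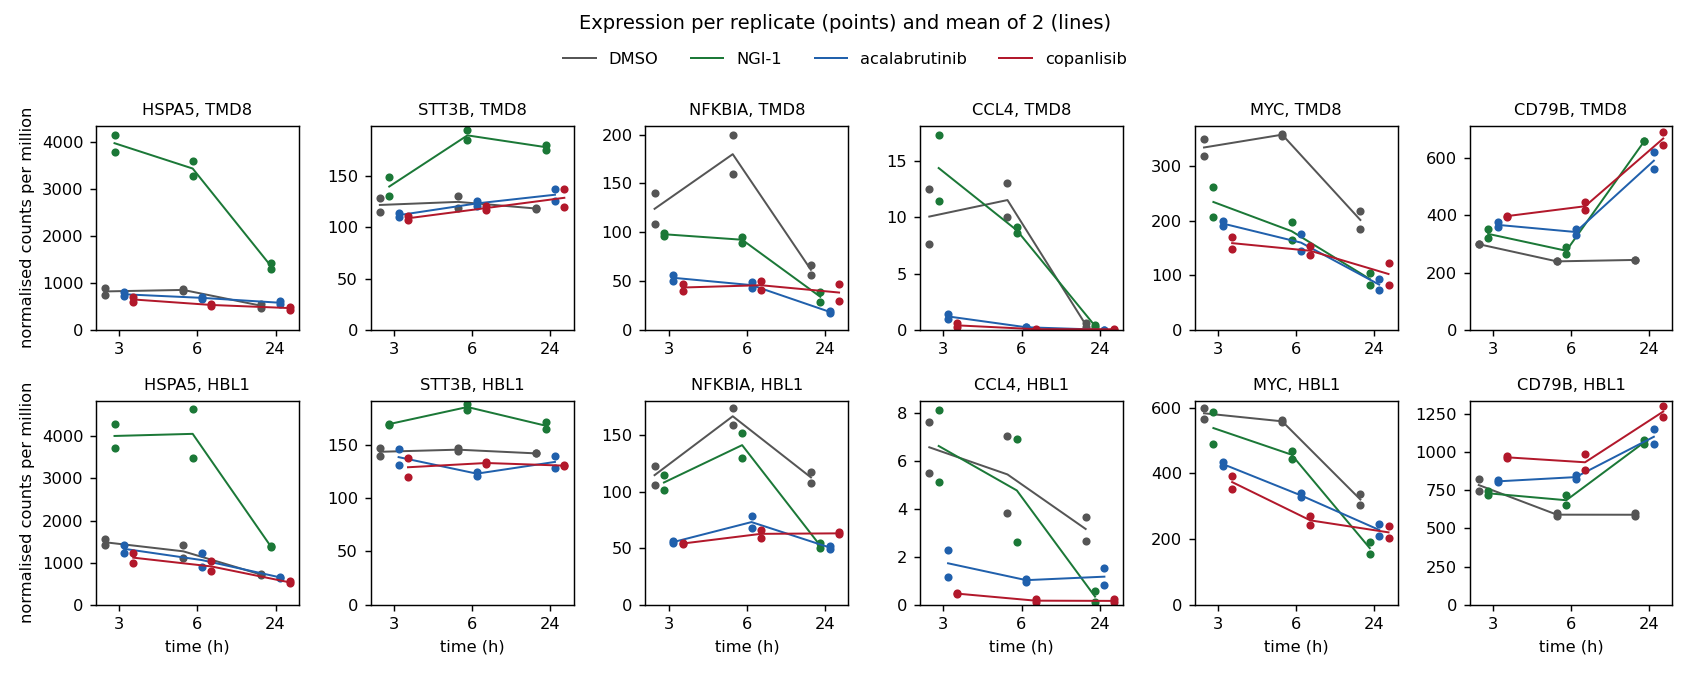
CPM of HSPA5, STT3B, NFKBIA, CCL4, MYC and CD79B in each replicate (points) with group means (lines) at 3, 6 and 24 h for DMSO and each compound in both lines. HSPA5 in TMD8 rose to 3970 CPM 3 h after NGI-1, and CD79B in TMD8 to 659 at 24 h.

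Among the strongest increases 24 h after NGI-1 was TTC17, which rose 3.69-fold in TMD8 (1.89 ± 0.1, adjusted p = 6.6e-20) and 3.27-fold in HBL1 (1.71 ± 0.1, adjusted p = 7.6e-18). NLRP7, an inflammasome-related gene, rose 9.92-fold in TMD8 (3.31 ± 0.33, adjusted p = 1.3e-10) and 7.05-fold in HBL1 (2.82 ± 0.24, adjusted p = 1.1e-11). PDIA2, a protein disulfide isomerase, rose 16-fold in TMD8 (4 ± 0.61, adjusted p = 4e-06). ERO1LB (ERO1B), which oxidises such isomerases, rose by 1.48 ± 0.3 in TMD8 and 2.04 ± 0.32 in HBL1. SUSD3 rose by 2.07 ± 0.31 and 2.28 ± 0.26, SLC6A16 by 2.3 ± 0.27 and 1.76 ± 0.19 in TMD8 and HBL1. PECAM1 rose by 3.38 ± 0.58 and 1.8 ± 0.22, and the cytokine gene LTB by 1.68 ± 0.31 and 2.05 ± 0.43. The TMD8 DMSO libraries held only 4 PECAM1 reads in all, so the size of that rise is uncertain. CEACAM1 rose in TMD8 by 2.48 ± 0.27. In HBL1, where the DMSO libraries held 1 read, the ratio was 24.3 (95% interval 3.96 to 999, counting error alone), a call lost without DMSO replicate 1 (0.12) or NGI-1 replicate 2 (0.22). TNF fell 4.25-fold in TMD8 (-2.09 ± 0.21, adjusted p = 6.6e-10) and 6.91-fold in HBL1 (-2.79 ± 0.32, adjusted p = 3.4e-08). IL4I1 fell 16.5-fold (-4.04 ± 0.29) and 2.95-fold (-1.56 ± 0.16), and the cytokine subunit gene EBI3 fell by 1.76 ± 0.21 and 1.53 ± 0.17. DUSP2, a phosphatase gene, fell by 1.6 ± 0.19 in TMD8 and 3.52-fold in HBL1 (-1.82 ± 0.18). The ETS factor gene ETV4 fell by 1.78 ± 0.36 and 1.54 ± 0.22. EGR2 fell 5.01-fold (-2.32 ± 0.38, adjusted p = 9.2e-06) and IL10 by 2.72 ± 0.36 (adjusted p = 8.5e-07) in TMD8. CCL4 fell 9.31-fold in HBL1 (-3.22 ± 0.63, adjusted p = 0.00021).

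Acalabrutinib had lowered 47 genes and raised 0 in TMD8 by 3 h. In HBL1 it had lowered 27 and raised 4. By edgeR 691 genes in TMD8 had an unadjusted p under 0.05, and DESeq2 called 1 gene higher and 53 lower. Without the filter 2 were higher and 78 lower there. After 6 h, 236 genes were higher and 389 lower in TMD8, and 341 higher and 438 lower in HBL1. After 24 h the numbers were 2127 and 2145 in TMD8 (457 and 370 at least 2-fold). In HBL1 they were 1045 and 1581 (275 and 76 at least 2-fold). In TMD8 the 47 at 3 h became 25, 14 and 15, and the 625 at 6 h became 364, 240 and 231, without acalabrutinib replicate 1, acalabrutinib replicate 2 and DMSO replicate 1. The 4272 at 24 h stayed between 2894 and 3685. In HBL1 the 31 at 3 h became 12, 11, 12 and 20 without acalabrutinib replicate 1, acalabrutinib replicate 2, DMSO replicate 1 and DMSO replicate 2. The 779 at 6 h in HBL1 became 299, 271 and 233, and the 2626 at 24 h became 1486, 1749 and 1254, without acalabrutinib replicate 1, acalabrutinib replicate 2 and DMSO replicate 1.

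NF-kB targets fell within 3 h of acalabrutinib. NFKBIA, which encodes the NF-kB inhibitor IκBα, fell 2.34-fold in TMD8 (-1.22 ± 0.16, adjusted p = 1.7e-05) and 2.07-fold in HBL1 (-1.05 ± 0.15, adjusted p = 0.00042) at 3 h. NFKBID fell by 1.58 ± 0.18 (adjusted p = 3.4e-06) and 1.1 ± 0.16 (adjusted p = 0.00045) at 3 h. At 6 h NFKBID had fallen 10.6-fold in TMD8. In TMD8 at 3 h TNF fell 4.65-fold (-2.22 ± 0.16, adjusted p = 2e-12), EGR2 fell 9.61-fold (-3.26 ± 0.29, adjusted p = 1.2e-09). The chemokine gene CCL4 fell 8.45-fold (-3.08 ± 0.42, adjusted p = 1.2e-05), from 10.1 ± 3.44 to 1.19 ± 0.324 CPM (mean ± SD, n = 2 libraries). Of 24 NF-kB targets, 0 were higher and 10 lower in TMD8 at 3 h (13 lower over the list alone). The median was -0.45 (camera adjusted p = 2.9e-35, 8.3e-05 with an estimated correlation). In HBL1, 0 were higher and 4 lower (16 lower over the list alone), with a median of -0.4 (1.5e-29, 0.00018 with an estimated correlation). At 6 h the median was -0.99 in TMD8 (0 higher, 18 lower, 21 lower over the list alone, 1.5e-48, 1.6e-05 with an estimated correlation). In HBL1 it reached -0.9 (0 higher, 20 lower, 1 and 21 over the list alone, 1.5e-33, 8.3e-05 with an estimated correlation). At 24 h the list remained at -0.71 in TMD8 (2 higher, 17 lower, 2.6e-07, 0.049 with an estimated correlation). It remained at -0.6 in HBL1 (1 higher, 14 lower, 2 and 15 over the list alone, 1.5e-08, 0.031 with an estimated correlation).

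At 24 h acalabrutinib had raised NLRP7 12.1-fold in TMD8 (3.59 ± 0.32, adjusted p = 4.7e-12) and 9.14-fold in HBL1 (3.19 ± 0.24, adjusted p = 2.1e-13). VPREB3, a gene of the B cell identity and receptor pathway list, rose by 2.88 ± 0.43 and 3.46 ± 0.52. The transcriptional inhibitor gene ID3 rose by 2.26 ± 0.27 and 1.97 ± 0.25. SUSD3 rose by 2.57 ± 0.29 and 2.98 ± 0.25, SLC6A16 by 2.58 ± 0.26 and 1.9 ± 0.19, and TAS1R3 by 5.05 ± 0.37 and 2.18 ± 0.5. CCL22, a chemokine gene, fell 40.9-fold in TMD8 (-5.35 ± 0.66) and 6.79-fold in HBL1 (-2.76 ± 0.47). SLC16A9 fell 9.45-fold (-3.24 ± 0.26) and 5.68-fold (-2.51 ± 0.4), and EBI3 fell 12.5-fold (-3.65 ± 0.27) and by 1.69 ± 0.17. MIRHG2 (MIR155HG), the host transcript of miR-155, fell by 2.83 ± 0.23 and 1.93 ± 0.19, and LYSMD2 fell by 1.64 ± 0.31 and 1.94 ± 0.33. IRF4, a survival factor of this lymphoma type, fell by 1.33 ± 0.14 in TMD8 and 0.69 ± 0.14 in HBL1. EGR2 in TMD8 went from 210 reads in the DMSO libraries to 2 reads, a ratio of 97.9 (95% interval 26.8 to 814).

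Copanlisib changed more genes at 3 h than the other compounds. In TMD8 91 were higher and 147 lower, and in HBL1 118 higher and 190 lower. By 6 h 969 genes were higher and 1030 lower in TMD8, and 583 higher and 741 lower in HBL1. By 24 h the numbers were 2166 and 2216 in TMD8 (484 and 275 at least 2-fold) and 1741 and 2450 in HBL1 (488 and 135 at least 2-fold). In TMD8 the 238 at 3 h became 122, 155 and 120, and the 1999 at 6 h became 1232, 959 and 955, without copanlisib replicate 1, copanlisib replicate 2 and DMSO replicate 1. The 4382 at 24 h became 2688 without copanlisib replicate 2. In HBL1 the 308 at 3 h became 196, 110, 92 and 195 without copanlisib replicate 1, copanlisib replicate 2, DMSO replicate 1 and DMSO replicate 2. The 1324 at 6 h in HBL1 became 635 and 637 without copanlisib replicate 2 and DMSO replicate 1. The 4191 at 24 h became 2576 without DMSO replicate 1.

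3 h after copanlisib CCL4 fell 25.2-fold in TMD8 (-4.66 ± 0.52) and 13.7-fold in HBL1 (-3.78 ± 0.52), and CCL3 fell 13.1-fold in TMD8 (-3.71 ± 0.54). TNF fell 10.2-fold in TMD8 (-3.36 ± 0.17) and 5.69-fold in HBL1 (-2.51 ± 0.33, adjusted p = 3e-06). IL10 fell 8.05-fold in TMD8 (-3.01 ± 0.32), and EGR2 fell 9.14-fold in TMD8 (-3.19 ± 0.28). NFKBIA fell by 1.52 ± 0.16 and 1.08 ± 0.15 in TMD8 and HBL1. KLHL24, a ubiquitin ligase adaptor gene, rose by 1.02 ± 0.15 in TMD8 (adjusted p = 1.3e-05) and 1.27 ± 0.12 in HBL1 (adjusted p = 5e-10). The chemokine receptor gene CXCR4 rose by 1.03 ± 0.1 in TMD8 (adjusted p = 2.7e-09), and the kinase gene NUAK2 by 1.83 ± 0.28 in TMD8 (adjusted p = 3.5e-05). In HBL1, CXCR4 rose by 0.96 ± 0.16 (adjusted p = 0.00022), a call lost without copanlisib replicate 2 (0.068). NUAK2 rose there by 1.07 (adjusted p = 0.0016), a call lost without DMSO replicate 2 (0.056). NF-kB targets had a median of -0.67 in TMD8 at 3 h (1 higher, 13 lower of 24, 1 and 18 over the list alone, camera adjusted p = 1.2e-26, 0.00029 with an estimated correlation). In HBL1 it was -0.41 (0 higher, 12 lower, 15 lower over the list alone, 3.2e-22, 0.0005 with an estimated correlation). At 6 h it stood at -1.05 in TMD8 (1 higher, 19 lower, 3 and 20 over the list alone, 5.4e-26, 0.00031 with an estimated correlation). HBL1 stood at -1.08 (0 higher, 20 lower, 1 and 22 over the list alone, 1.8e-34, 8.3e-05 with an estimated correlation). At 24 h the list was lower in HBL1 (2 higher, 13 lower, median -0.45, 0.00015), a call lost with an estimated correlation (adjusted p = 0.15). In TMD8 camera did not call it (4 higher, 10 lower, median -0.43, adjusted p = 0.054), whereas fry, which does not compare a list with other genes, called it lower (0.027).

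24 h after copanlisib NLRP7 was 9.36-fold higher in TMD8 (3.23 ± 0.33) and 13-fold higher in HBL1 (3.7 ± 0.23, adjusted p = 3.3e-16). In HBL1 it rose from 3.97 ± 0.168 to 51.8 ± 6.47 CPM (mean ± SD, n = 2 libraries). LTB rose 8.43-fold in TMD8 (3.07 ± 0.28) and 13.7-fold in HBL1 (3.78 ± 0.36), and SUSD3 by 2.31 ± 0.3 and 3.43 ± 0.25. The surface antigen gene CD52 rose by 2.41 ± 0.56 and 2.21 ± 0.24, and TAS1R3 by 5.64 ± 0.36 and 2.33 ± 0.48. BBC3, which encodes the BH3-only protein PUMA, rose by 1.1 ± 0.18 in TMD8 and 1.29 ± 0.28 in HBL1. CCL22 fell 10.9-fold in TMD8 and 16.1-fold in HBL1, and EBI3 fell by 2.71 and 1.84. SLC16A9 fell by 1.81 and 2.43, and the AP-1 factor gene BATF3 by 1.45 ± 0.25 and 1.57 ± 0.29. TPRG1 fell by 2.93 ± 0.38 and TGM2 by 1.68 ± 0.17 in TMD8. LRRC32 had 0 reads in the TMD8 copanlisib libraries and was at least 11.4-fold lower than in DMSO, a bound that takes 3 reads as the floor and covers counting error alone.

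All 3 compounds converged at 24 h on lower MYC and higher B cell genes. MYC fell 2.16-fold in TMD8 (-1.11 ± 0.16, adjusted p = 4.5e-06) and 1.86-fold in HBL1 (-0.9 ± 0.16, adjusted p = 0.00011) with NGI-1. With acalabrutinib it fell 2.42-fold in TMD8 (-1.28 ± 0.16) and with copanlisib by 0.97. In TMD8 it went from 201 ± 23.8 CPM in DMSO to 93.4 ± 15.3 with NGI-1, 83 ± 14.4 with acalabrutinib and 102 ± 27.4 with copanlisib (mean ± SD, n = 2 libraries). In HBL1 the MYC decreases of 0.49 with acalabrutinib (adjusted p = 0.023) and 0.54 with copanlisib (adjusted p = 0.008) were lost without DMSO replicate 1 (0.2 and 0.098), without acalabrutinib replicate 2 (0.22) or without copanlisib replicate 2 (0.12). The 27 MYC target and ribosome biogenesis genes fell with NGI-1 to a median of -0.66 in TMD8 (0 higher, 27 lower, camera adjusted p = 1e-23, 0.01 with an estimated correlation). In HBL1 the median was -0.53 (0 higher, 25 lower, 26 lower over the list alone, 2.4e-24, 0.0097 with an estimated correlation). Acalabrutinib took them to -0.67 in TMD8 (0 higher, 27 lower, 1.7e-24, 0.0097 with an estimated correlation) and -0.38 in HBL1 (0 higher, 21 lower, 24 lower over the list alone, 1.3e-15, 0.039 with an estimated correlation). Copanlisib took them to -0.59 in TMD8 (0 higher, 26 lower, 1.1e-19, 0.02 with an estimated correlation) and -0.5 in HBL1 (0 higher, 27 lower, 1.4e-17, 0.029 with an estimated correlation). The mitochondrial chaperone gene HSPD1 fell by 0.9 ± 0.07 and 0.63 with NGI-1, 0.86 and 0.6 with acalabrutinib and 0.94 and 0.81 with copanlisib in TMD8 and HBL1. The nucleolar gene NCL fell by 0.71 ± 0.11 and 0.59, 0.78 and 0.57, and 0.71 and 0.75.

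CD79B, the B cell receptor signalling chain mutated in both of these lines, rose at 24 h by 1.43 ± 0.07 in TMD8 (2.7-fold, adjusted p = 9.8e-20) and 0.86 ± 0.07 in HBL1 (1.81-fold) with NGI-1. Acalabrutinib raised it 2.42-fold and 1.86-fold and copanlisib 2.74-fold and 2.15-fold. Its level in TMD8 went from 244 ± 0.243 CPM to 659 ± 1.92, 590 ± 42.1 and 668 ± 30.7 with NGI-1, acalabrutinib and copanlisib (mean ± SD, n = 2 libraries). POU2AF1, a B cell coactivator gene, rose by 0.84 ± 0.09 and 0.69 ± 0.08 with NGI-1, 0.85 and 0.79 with acalabrutinib and 0.96 and 1.05 with copanlisib in TMD8 and HBL1. CD72 rose by 1.05 ± 0.09 and 0.56 ± 0.1, 0.99 and 0.53, and 1.12 and 0.97. Among 26 B cell identity and receptor pathway genes, NGI-1 raised 18 and lowered 0 in TMD8 (18 and 1 over the list alone). The median was 0.45 (camera adjusted p = 9.7e-11, 0.012 with an estimated correlation). In HBL1 it raised 12 and lowered 1 (13 and 1 over the list alone). The median there was 0.22 (8.6e-07), a call lost with an estimated correlation (adjusted p = 0.055). Acalabrutinib gave a median of 0.37 in TMD8 (15 higher, 0 lower, 17 and 1 over the list alone, 3e-08, 0.031 with an estimated correlation). In HBL1 it gave 0.18 (11 higher, 2 lower, 1.7e-06), a call lost with an estimated correlation (adjusted p = 0.065). Copanlisib gave 0.39 in TMD8 (16 higher, 0 lower, 17 over the list alone, 1.6e-09, 0.02 with an estimated correlation). In HBL1 it gave 0.36 (17 higher, 1 lower, 17 and 2 over the list alone, 1.2e-08, 0.028 with an estimated correlation).

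FOXO targets also rose at 24 h in every condition. Of 17 tested, NGI-1 raised 9 and lowered 1 in TMD8 (10 and 2 over the list alone, median 0.6, camera adjusted p = 0.0004, 0.013 with an estimated correlation). It raised 11 and lowered 0 in HBL1 (12 over the list alone, median 0.72, 2.2e-08, 0.00035 with an estimated correlation). Acalabrutinib raised 9 and lowered 2 in TMD8 (11 and 2 over the list alone, median 0.61, 0.00094, 0.02 with an estimated correlation). In HBL1 it raised 9 and lowered 0 (median 0.51, 1.1e-06, 0.0012 with an estimated correlation). Copanlisib raised 10 and lowered 1 in TMD8 (11 and 1 over the list alone, median 0.5, 0.00017, 0.0097 with an estimated correlation). In HBL1 it raised 12 and lowered 0 (13 over the list alone, median 0.76, 5.4e-08, 0.00043 with an estimated correlation). Already at 3 h the list rose with copanlisib, with a median of 0.24 in TMD8 (3 higher, 0 lower, 5 over the list alone, 2.2e-06, 0.0016 with an estimated correlation). HBL1 showed 0.34 (3 higher, 0 lower, 8 over the list alone, 6e-07, 0.00096 with an estimated correlation). With NGI-1 at 3 h in TMD8 the list was called higher (adjusted p = 0.033) while its median was -0.02 and its mean 0.15. That call was lost with an estimated correlation (adjusted p = 0.13) and without DMSO replicate 1 (0.056), DMSO replicate 2 (0.097) or NGI-1 replicate 1 (0.15). CCNG2, a FOXO target that slows the cell cycle, rose by 1.04 ± 0.16 and 1.81 ± 0.24 with NGI-1, 1 and 1.25 with acalabrutinib and 0.96 and 1.53 with copanlisib at 24 h in TMD8 and HBL1. BTG1, an antiproliferative gene, rose by 0.87 ± 0.11 and 0.93, 0.83 and 0.74, and 0.87 and 1.14.

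Glycolysis and G1/S genes fell at 24 h. LDHA, which encodes a lactate dehydrogenase subunit, fell by 1 ± 0.09 and 0.76 with NGI-1, 0.81 and 0.68 with acalabrutinib and 0.92 and 0.97 with copanlisib in TMD8 and HBL1. HK2 fell by 1.08 ± 0.11 and 0.72, 1.08 and 0.54, and 0.94 and 0.77. The 20 glycolysis genes had a median of -0.52 with NGI-1 in TMD8 (2 higher, 14 lower, camera adjusted p = 2.5e-06, lost at adjusted p = 0.11 with an estimated correlation). The HBL1 median was -0.36 (0 higher, 11 lower, 13 lower over the list alone, 2.5e-06, lost at adjusted p = 0.11). With acalabrutinib they reached -0.57 in TMD8 (3 higher, 15 lower, 1.4e-06, lost at adjusted p = 0.098). In HBL1 they reached -0.29 (0 higher, 10 lower, 1 and 11 over the list alone, 0.0002, lost at adjusted p = 0.21). With copanlisib they reached -0.58 in TMD8 (3 higher, 14 lower, 2.4e-06, lost at adjusted p = 0.11). In HBL1 they reached -0.45 (0 higher, 12 lower, 1 and 13 over the list alone, 2.3e-05, lost at adjusted p = 0.15). Of 21 genes of G1/S and DNA replication, NGI-1 lowered 19 in TMD8 (0 higher, 20 lower over the list alone, median -0.63, 7.3e-11, lost at adjusted p = 0.19 with an estimated correlation). It lowered 14 in HBL1 (0 higher, 18 lower over the list alone, median -0.41, 2.4e-09, lost at adjusted p = 0.23). Acalabrutinib lowered 17 in TMD8 (0 higher, 19 lower over the list alone, median -0.57, 5e-09, lost at adjusted p = 0.24) and 20 in HBL1 (0 higher, 21 lower over the list alone, median -0.64, 2.9e-17, lost at adjusted p = 0.076). Copanlisib lowered 15 in TMD8 (0 higher, 1 and 17 over the list alone, median -0.46, 3.3e-06, lost at adjusted p = 0.39). It lowered 21 in HBL1 (0 higher, median -0.74, 3.9e-15, lost at adjusted p = 0.1). MCM10, a replication gene, fell by 0.96 ± 0.12 and 0.61, 0.81 and 0.82, and 0.74 and 1.05 with NGI-1, acalabrutinib and copanlisib. The 20 G2/M genes fell in TMD8 at 24 h with NGI-1 (0 higher, 9 lower, 10 lower over the list alone, median -0.21, 0.0019, lost at adjusted p = 0.53 with an estimated correlation). They were not called with NGI-1 in HBL1 (1 higher, 1 lower, 0 and 1 over the list alone, median -0.09, adjusted p = 0.55). Nor were they with acalabrutinib in TMD8 (1 higher, 7 lower, 1 and 8 over the list alone, median -0.12, adjusted p = 0.063). Camera called the list higher at 3 and 6 h in both lines with copanlisib and acalabrutinib, and at 6 h in TMD8 with NGI-1. These calls were lost with an estimated correlation. With copanlisib in TMD8 the median was 0.35 at 6 h (13 higher, 0 lower, 1.9e-08, lost at adjusted p = 0.19). At 24 h the median was -0.38 (0 higher, 12 lower, 14 lower over the list alone, 1.1e-06, lost at adjusted p = 0.27). At 24 h in HBL1 they fell with copanlisib (0 higher, 18 lower, 19 lower over the list alone, median -0.55, 2.2e-11, lost at adjusted p = 0.11) and acalabrutinib (0 higher, 13 lower, 15 lower over the list alone, median -0.42, 5.3e-10, lost at adjusted p = 0.14).

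**Figure D3:**
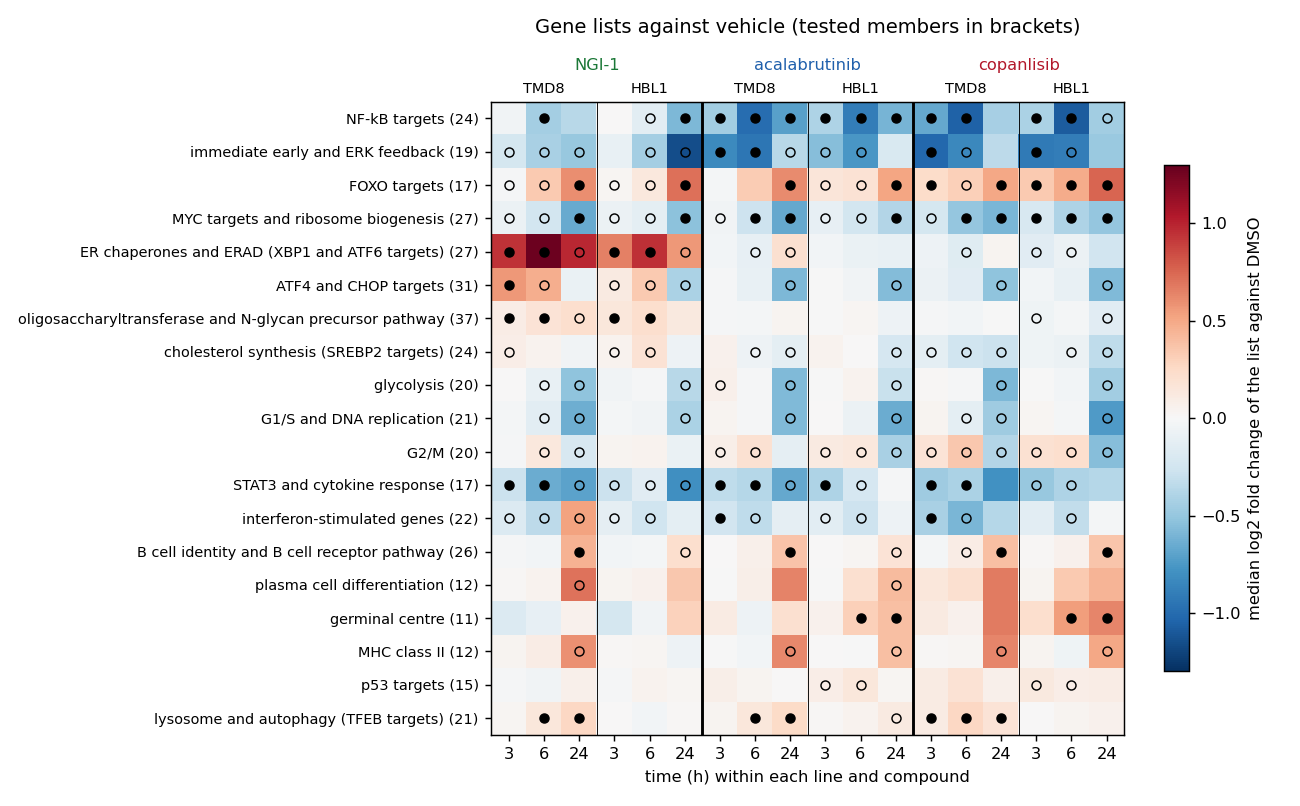
Median log2 fold change against DMSO (colour) of 19 gene lists in 18 comparisons of compound, line and time, with an open circle for camera adjusted p under 0.05 and a filled circle where the call also held with an estimated correlation. The ER chaperone list reached a median of 1.27 with NGI-1 in TMD8 at 6 h, and the NF-kB list -1.08 with copanlisib in HBL1 at 6 h.

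Many 24 h changes were common to TMD8 and HBL1. NGI-1 raised 703 and lowered 1033 genes in both lines and moved 39 in opposite directions, against 170.6 and 233.7 for independent calls. Acalabrutinib raised 582 and lowered 1025 in both (43 opposite, against 160.1 and 244.3), and copanlisib raised 898 and lowered 1391 (76 opposite, against 271.7 and 391.1). Log2 fold changes of the lines correlated at r = 0.43, 0.42 and 0.46 for NGI-1, acalabrutinib and copanlisib. At 3 h, 29 genes were higher and 0 lower in both lines with NGI-1, 0 and 12 with acalabrutinib, and 28 and 70 with copanlisib. At 6 h the numbers were 103 and 7, 75 and 183, and 306 and 479.

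The compounds also shared most of their 24 h changes within a line. NGI-1 and acalabrutinib changed 3235 genes the same way in TMD8 (1607 higher, 1628 lower, 4 in opposite directions, 332 and 318 for independent calls, r = 0.81), which is 76.6% of the genes that NGI-1 changed. They shared 1605 in HBL1 (620 higher, 985 lower, 7 opposite, 82 and 180 for independent calls, r = 0.66), or 60.1%. NGI-1 and copanlisib shared 3271 in TMD8 (1600 higher, 1671 lower, 6 opposite, 338 and 328 for independent calls, r = 0.8). In HBL1 they shared 2113 (814 higher, 1299 lower, 18 opposite, 137 and 278 for independent calls, r = 0.73). Acalabrutinib and copanlisib shared 3363 in TMD8 (1650 higher, 1713 lower, 8 opposite, 332 and 342 for independent calls, r = 0.83). In HBL1 they shared 2429 (955 higher, 1474 lower, 0 opposite, 131 and 279 for independent calls, r = 0.81). Because both compounds were set against the same DMSO libraries, part of the excess may come from shared controls. In 20 simulations with no change, shared controls alone gave 0.05 shared calls or fewer on average and r = 0.48 in TMD8 and 0.5 in HBL1. The simulated r and covariance covered only genes with a mean log2 CPM of at least 1. The covariance of the fold changes was 0.263, 0.254 and 0.289 in TMD8 for NGI-1 with acalabrutinib, NGI-1 with copanlisib and acalabrutinib with copanlisib, against simulated values of 0.0356, 0.0359 and 0.0353. In HBL1 it was 0.158, 0.203 and 0.221, against 0.0382, 0.0379 and 0.0374. In HBL1 the shared counts fell when certain libraries were left out, although a group of 1 sample has less power by itself. The 1605 became 1023 without acalabrutinib replicate 1 and 661 without DMSO replicate 1. The 2113 became 1048, 1384 and 1367 without DMSO replicate 1, NGI-1 replicate 1 and NGI-1 replicate 2. The 2429 became 1410 without acalabrutinib replicate 1 and 1161 without DMSO replicate 1. All 3 compounds raised 1404 and lowered 1480 genes in TMD8, 602 and 968 in HBL1, and 344 and 676 in both lines.

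Set directly against the kinase inhibitors at 24 h, NGI-1 was marked by endoplasmic reticulum genes. HSPA5 was higher with NGI-1 than with acalabrutinib by 1.24 ± 0.16 in TMD8 and 1.09 ± 0.16 in HBL1. Against copanlisib it was higher by 1.55 and 1.38. ARMET (MANF), a secreted stress factor, was higher by 1.25 and 1.21 against acalabrutinib and by 1.53 and 1.43 against copanlisib. TTC17 was higher by 1.37 ± 0.09 and 1.48 ± 0.1 and by 1.37 and 1.35. STT3B was higher by 0.44 and 0.33 against acalabrutinib and 0.47 and 0.37 against copanlisib. The 27 chaperone and degradation genes were higher with NGI-1 than with acalabrutinib in TMD8 (19 higher, 0 lower, 22 over the list alone, median 0.74, camera adjusted p = 3.4e-57, 0.0023 with an estimated correlation). The same held in HBL1 (15 higher, 0 lower, 21 over the list alone, median 0.51, 1.9e-31, 0.018 with an estimated correlation). Against copanlisib the medians were 0.79 (19 higher, 0 lower, 20 over the list alone, 1.1e-64, 0.0014 with an estimated correlation) in TMD8 and 0.64 in HBL1 (18 higher, 0 lower, 20 over the list alone, 7.4e-35, 0.013 with an estimated correlation). LTB was lower with NGI-1 than with copanlisib by 1.4 ± 0.24 in TMD8 and 1.74 ± 0.27 in HBL1. In total 152 genes were higher and 28 lower with NGI-1 than with acalabrutinib in TMD8 and 223 and 228 in HBL1. Against copanlisib the numbers were 148 and 40 in TMD8 and 369 and 316 in HBL1. Acalabrutinib and copanlisib differed least, with 21 genes higher and 43 lower with acalabrutinib in TMD8 and 6 and 8 in HBL1. In TMD8 the 180 became 80, 90 and 100 without acalabrutinib replicate 2, NGI-1 replicate 1 and NGI-1 replicate 2. The 188 became 105, 103 and 108 without copanlisib replicate 2, NGI-1 replicate 1 and NGI-1 replicate 2. The 64 became 41 and 32 without acalabrutinib replicate 1 and copanlisib replicate 1. In HBL1 the 451 became 173, 233, 165 and 213 without acalabrutinib replicates 1 and 2 and NGI-1 replicates 1 and 2. The 685 became 318, 387, 280 and 380 without copanlisib replicates 1 and 2 and NGI-1 replicates 1 and 2. The 14 became 23, 2 and 2 without acalabrutinib replicate 1, acalabrutinib replicate 2 and copanlisib replicate 1.

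**Figure D4:**
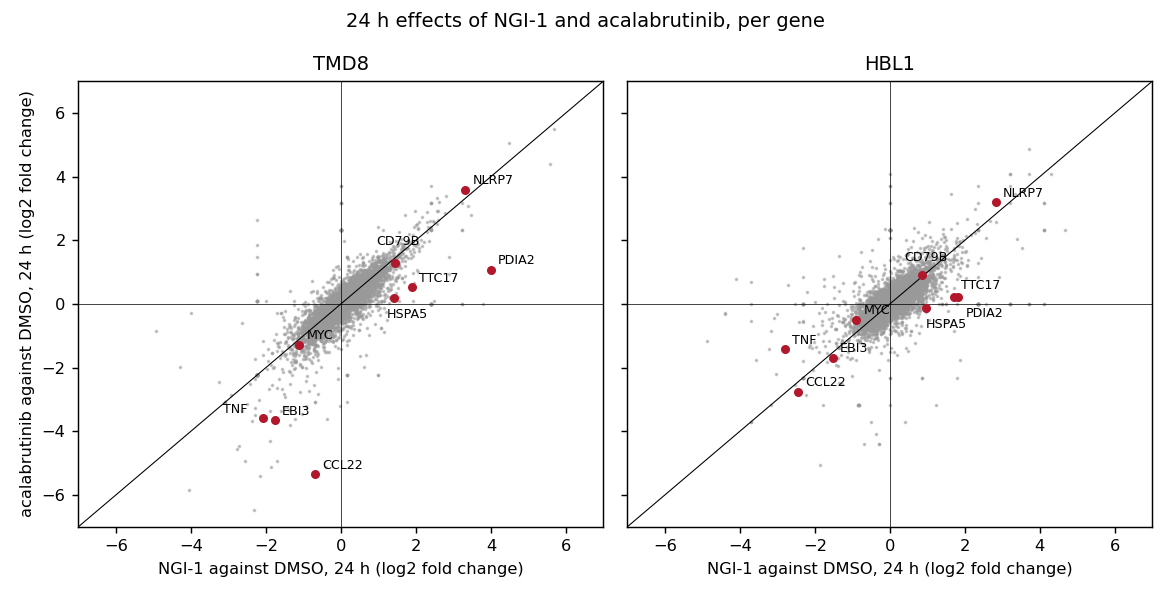
Log2 fold change against DMSO at 24 h of NGI-1 (horizontal) and acalabrutinib (vertical) for 11605 genes in each line, with equal change on the diagonal and named genes in red. The changes correlated at r = 0.81 in TMD8 and 0.66 in HBL1 over all tested genes, while HSPA5 and TTC17 lay off the diagonal.

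Vehicle cultures changed with time as well. Between 3 and 24 h of DMSO, 2346 genes rose and 2202 fell in TMD8, and 2874 rose and 2642 fell in HBL1. The TMD8 total of 4548 became 2987 without the 24 h DMSO replicate 2 and 2730 without the 3 h DMSO replicate 1. The HBL1 total of 5516 stayed between 4008 and 4376. Camera did not call the marker lists of other cell types with any compound. Over the 18 comparisons the smallest camera adjusted p was 0.14 for the 3 tested T and NK cell genes, 0.18 for the 2 tested myeloid genes and 0.098 for the 8 tested stromal and epithelial genes. By fry the T and NK cell list was called higher in TMD8 at 24 h with NGI-1, acalabrutinib and copanlisib (1 higher, 0 lower each, adjusted p = 0.0042, 0.0033 and 0.022). At 6 h fry called it with acalabrutinib (0 higher, 0 lower, 0.027) and copanlisib (0 higher, 0 lower, 1 higher over the list alone, 0.027). Fry called the myeloid list lower in TMD8 at 24 h with acalabrutinib (0 higher, 1 lower, 0.011) and copanlisib (0 higher, 1 lower, 0.028), and the stromal and epithelial list higher with NGI-1 in HBL1 at 24 h (1 higher, 0 lower, 0.027). Some of these genes marked the lines instead, with median CPM in TMD8 and HBL1 of 0.219 and 39.2 for CD247, 96.7 and 0 for CDH1, 0 and 9.87 for EPCAM, and 8.47 and 0 for KRT8. CD3D, CD14 and LYZ did not exceed 0.224, 0.336 and 0.353 CPM in any library.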

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

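The tests of shared DMSO libraries and of low interferon-stimulated genes in the TMD8 vehicle were chosen after the result was seen, and the other tests of this section were written before they were run. NGI-1 shared most of its 24 h changes with each kinase inhibitor (r = 0.81 and 0.8 in TMD8, 0.66 and 0.73 in HBL1). If shared DMSO libraries were the whole cause, the simulated covariance would reach the observed one. It reached at most 0.242 of it over the 6 comparisons. Genes with few reads were left out of the simulated value only, so the part of shared controls stays open. An earlier bound of 0.2 was missed, and the bound for the whole cause was set after seeing 0.242. If the change of the vehicle cultures after 6 h were the cause, the shared genes would not differ from the 6 h vehicle, yet a share of at least 0.56 was called the same way against it (0.73 in TMD8, 0.56 to 0.68 in HBL1), although the vehicle itself moved the other way in 23.6% of 2884 genes in TMD8 and 37.6% of 1570 in HBL1, and without the 22% and 13% that it moved the same way the shares were 0.65 to 0.66 and 0.49 to 0.63, so it may account for part of the change. The reason for the rest was not tested and stays open, as does the effect of dose.

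Interferon-stimulated genes were higher 24 h after NGI-1 in TMD8 (14 of 22 higher, 1 lower, median 0.52, camera adjusted p = 2e-07), a call lost with an estimated correlation (adjusted p = 0.073), and not in HBL1 (2 higher, 5 lower, 2 and 6 over the list alone, median -0.13, adjusted p = 0.75). The line difference was called (7 higher, 0 lower, 18 over the list alone, median 0.61, 2.1e-13, 0.028 with an estimated correlation), although NGI-1 itself had lowered the list in TMD8 at 3 h (0 higher, 0 lower, median -0.18, 0.00093, lost at adjusted p = 0.28 with an estimated correlation, and without DMSO replicate 1 (0.54) or NGI-1 replicate 2 (0.25)) and 6 h (0 higher, 4 lower, 8 lower over the list alone, median -0.34, 1.1e-06, lost at adjusted p = 0.098 with an estimated correlation). If 1 library were the cause, the median would fall without it, but it stayed at 0.48 or more without each of the 4 libraries. Low values in the vehicle would raise the list with the kinase inhibitors too, and the larger of their medians was -0.12, but this decides nothing because these compounds had lowered the list in TMD8 at 3 h, acalabrutinib by a median of -0.25 (0 higher, 4 lower, 6 lower over the list alone, 5.4e-12, 0.018 with an estimated correlation) and copanlisib by -0.42 (0 higher, 6 lower, 1 and 11 over the list alone, 6.8e-09, 0.044 with an estimated correlation), so low vehicle values stay open.

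NF-kB targets fell at 3 h with the kinase inhibitors, whereas with NGI-1 their medians were -0.05 in TMD8 (0 higher, 0 lower of 24, adjusted p = 0.38) and 0 in HBL1 (0 higher, 0 lower, mean 0.02 with a test direction of lower, adjusted p = 0.66). If this were chance between separate tests, the direct comparisons would show no difference, but the list was higher with NGI-1 in all 4 of them, and the largest adjusted p with an estimated correlation was 0.00096. If 1 library were the cause, some pairing of an NGI-1 library with a kinase inhibitor library would lack the difference, but the lowest median of 16 pairings was 0.3. The later fall with NGI-1, to medians of -0.44 at 6 h in TMD8 (0 higher, 9 lower, 2 and 13 over the list alone, 1.4e-11, 0.01 with an estimated correlation) and -0.58 at 24 h in HBL1 (1 higher, 15 lower, 2 and 18 over the list alone, 4.7e-09, 0.026 with an estimated correlation), was less clear elsewhere. In HBL1 at 6 h the median was -0.14 (0 higher, 0 lower, 0.0087, lost at adjusted p = 0.35 with an estimated correlation, and without DMSO replicate 1 (0.24) or NGI-1 replicate 2 (0.18)), and in TMD8 at 24 h the list was called by fry (0.049) but not by camera (3 higher, 8 lower, median -0.36, adjusted p = 0.061), so the reason for the later course stays open.

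The compound effect differed between the lines (TMD8 minus HBL1) in 2, 3 and 357 genes with NGI-1 at 3, 6 and 24 h, 0, 21 and 581 with acalabrutinib and 8, 78 and 586 with copanlisib. For acalabrutinib at 3 h the edgeR count was 0, with 393 genes at an unadjusted p under 0.05 and 0 by DESeq2. The NGI-1 count of 2 became 0 without the TMD8 DMSO replicate 2 and 1 without the HBL1 DMSO replicate 2, the HBL1 NGI-1 replicates 1 or 2, the TMD8 DMSO replicate 1 or the TMD8 NGI-1 replicate 1. Its count of 3 became 0 without the HBL1 DMSO replicate 2, the HBL1 NGI-1 replicate 1, the TMD8 DMSO replicate 1 or the TMD8 NGI-1 replicates 1 or 2, 6 without the HBL1 NGI-1 replicate 2 and 5 without the TMD8 DMSO replicate 2. Its count of 357 became 217, 216, 206, 198 and 177 without the HBL1 DMSO replicate 1, HBL1 NGI-1 replicate 1, HBL1 NGI-1 replicate 2, TMD8 DMSO replicate 2 and TMD8 NGI-1 replicate 1. For acalabrutinib 21 became 12 without the HBL1 acalabrutinib replicate 2 or the HBL1 DMSO replicate 1, and 581 became 345 without the TMD8 DMSO replicate 2. For copanlisib 8 became 5, 3, 14, 4 and 3 without the HBL1 copanlisib replicate 2, HBL1 DMSO replicate 1, HBL1 DMSO replicate 2, TMD8 DMSO replicate 1 and TMD8 DMSO replicate 2. Its 78 became 40, 41, 48, 40 and 39 without the HBL1 copanlisib replicate 2, HBL1 DMSO replicate 1, TMD8 copanlisib replicate 1, TMD8 copanlisib replicate 2 and TMD8 DMSO replicate 1, and its 586 became 372, 384, 364 and 331 without the HBL1 copanlisib replicate 1, HBL1 copanlisib replicate 2, HBL1 DMSO replicate 1 and TMD8 DMSO replicate 2.

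With NGI-1 at 24 h the effect on the lectin gene CLEC17A was higher in TMD8 by 1.41, on IRF8 by 1.25 and on NAPSB by 0.91, and lower on UAP1 by 1.01 (-1.01), on SEMA4A (-1.26) and on the kinase gene SRC (-1.56). Acalabrutinib differed for CLEC17A (1.01), CDC42BPB (1.93), IRF8 (1.21), UAP1 (-1.58), IL4I1 (-5.16) and DUSP2 (-2.81), and copanlisib for CLEC17A (1.1), the corepressor gene TLE1 (1.21), CDC42BPB (1.89), UAP1 (-1.44), SEMA4A (-1.94) and BTG2 (-0.93). EGR2 differed with acalabrutinib by -2.92 at 6 h, lost without the HBL1 acalabrutinib replicate 2 (0.68), the HBL1 DMSO replicate 1 (0.061) or the TMD8 acalabrutinib replicate 1 (0.07), and by -7.05 at 24 h, a value fitted on 2 reads. With copanlisib EGR2 differed by -2.71 at 6 h, lost without the HBL1 copanlisib replicate 1 (0.2), HBL1 copanlisib replicate 2 (0.088), HBL1 DMSO replicate 1 (0.073) or TMD8 copanlisib replicate 1 (0.08), and by -3.76 at 24 h. MYC differed with acalabrutinib by -0.78 at 24 h (adjusted p = 0.038), lost without the HBL1 acalabrutinib replicate 1 (0.19), HBL1 DMSO replicate 1 (0.063), HBL1 DMSO replicate 2 (0.17), TMD8 acalabrutinib replicate 2 (0.22) or TMD8 DMSO replicate 1 (0.17). Lysosome and autophagy genes differed between the lines with NGI-1 by a median of 0.19 at 6 h (camera adjusted p = 0.00052, 0.011 with an estimated correlation) and 0.34 at 24 h (4.1e-08, 7.3e-05 with an estimated correlation), and with copanlisib by 0.11 at 3 h (0.0032, 0.028 with an estimated correlation), 0.28 at 6 h (2.8e-09, 4.6e-05 with an estimated correlation) and 0.2 at 24 h (0.0012, 0.019 with an estimated correlation).

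Between 3 and 24 h the compound effect changed for 1663 genes in TMD8 and 666 in HBL1 with NGI-1, 1998 and 549 with acalabrutinib and 1516 and 1293 with copanlisib. In TMD8 the NGI-1 effect moved by 0.39 for STT3B, 0.79 for PIK3CA, -1.46 for EGR2 and -0.87 for HSPA5, and in HBL1 by -0.78 for MYC, -1.02 for NFKBIA, -3.92 for CCL3, -3.25 for CCL4 and -3.02 for EGR2. The acalabrutinib effect moved in TMD8 by 0.67 for PIK3CA, -0.95 for IRF4 and -3.19 for EGR2 (fitted on 2 reads at 24 h), and in HBL1 by 1.95 for EGR2, while the copanlisib effect moved by 0.85 for NFKBIA in TMD8 and 2.02 for EGR2 in HBL1. In TMD8 the 1663 became 1022 without the 3 h DMSO replicate 1 and 950 without the 3 h NGI-1 replicate 2, the 1998 became 1303, 1176 and 1261 without the 24 h acalabrutinib replicate 2, the 3 h acalabrutinib replicate 2 and the 3 h DMSO replicate 1, and the 1516 became 866, 664, 987 and 852 without the 24 h copanlisib replicate 2, the 3 h copanlisib replicate 2, the 24 h DMSO replicate 1 and the 3 h DMSO replicate 1. In HBL1 the 666 became 279, 311, 358, 369 and 406 without the 24 h DMSO replicate 1, the 3 h DMSO replicate 2, the 24 h NGI-1 replicates 1 and 2 and the 3 h NGI-1 replicate 1. The 549 became 189, 309, 245 and 244 without the 24 h acalabrutinib replicate 1, the 3 h acalabrutinib replicate 1, the 24 h DMSO replicate 1 and the 3 h DMSO replicate 2, and the 1293 became 833, 759, 677 and 669 without the 24 h copanlisib replicate 1, the 3 h copanlisib replicate 1, the 24 h DMSO replicate 1 and the 3 h DMSO replicate 2.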

How the results depend on the processing

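RLE size factors moved 0 of 47 counts of called genes by more than 1.5-fold, and they changed the share of genes called higher by at most 7.0 points, from 41.5% to 48.5% with copanlisib in HBL1 at 24 h. DESeq2 moved 4 of 47: acalabrutinib in HBL1 at 3 h from 31 to 47, the line difference of NGI-1 at 6 h from 3 to 15, that of copanlisib at 3 h from 8 to 13, and acalabrutinib against copanlisib in HBL1 from 14 to 39. Without the filter 15 of 47 moved: NGI-1 in TMD8 at 3 h 161, in HBL1 101 at 3 h and 249 at 6 h, acalabrutinib at 3 h 80 in TMD8 and 88 in HBL1. Line differences at 3 and 6 h became 22 and 50 for NGI-1, 3 and 62 for acalabrutinib and 26 and 126 for copanlisib. Direct comparisons became 329 for NGI-1 against acalabrutinib and 301 against copanlisib in TMD8, and 145 in TMD8 and 57 in HBL1 for acalabrutinib against copanlisib. The stricter filter moved 1 of 47, acalabrutinib against copanlisib in HBL1 to 24. Separate fits moved 3 of 38: NGI-1 in HBL1 at 3 h to 13, and in TMD8 NGI-1 against acalabrutinib to 271 and acalabrutinib against copanlisib to 103. Replicates of the same number deviated alike within a line and time (r from 0.09 to 0.5, median 0.29, above 0.1 in 35 of 36). For pairs of groups of another line or time the median r was 0.03 to 0.1. The labels name no shared culture or day, and 1 of 36 pairs was not above 0.1. The main fit therefore did not pair the samples by number. If the numbers do mark a batch, the main fit left it in the spread, and its counts may be too low. Of 48 libraries 22 matched best within their own group and the other 26 matched 1 of the same number, a hint from the data that the numbers mark a shared batch. A replicate block moved 27 of 47 counts: NGI-1 in TMD8 205 at 3 h and 1020 at 6 h and in HBL1 123 and 346, acalabrutinib in TMD8 77 and 1040 and in HBL1 104 and 1227, copanlisib at 3 h 505 in TMD8 and 601 in HBL1. Of the counts with a 0, NGI-1 in HBL1 at 3 h split into 116 higher and 7 lower and acalabrutinib in TMD8 at 3 h into 2 and 75. Line differences became 9, 37 and 683 for NGI-1 at 3, 6 and 24 h, 75 and 979 for acalabrutinib at 6 and 24 h and 22, 169 and 974 for copanlisib. For 24 h minus 3 h in HBL1 they became 1337, 1164 and 1946 for NGI-1, acalabrutinib and copanlisib. Direct comparisons gave NGI-1 against acalabrutinib 360 in TMD8 and 797 in HBL1, NGI-1 against copanlisib 350 and 1165, and acalabrutinib against copanlisib 188 and 85. A block within each line and time, chosen after seeing the data, moved 38 of 45: NGI-1 in TMD8 508 at 3 h and 1843 at 6 h and in HBL1 307, 825 and 4334, acalabrutinib in TMD8 171 and 1705 and in HBL1 272, 2145 and 4215, copanlisib in TMD8 1015 and 3460 and in HBL1 1141 and 2818. There NGI-1 in HBL1 at 3 h split into 226 higher and 81 lower and acalabrutinib in TMD8 at 3 h into 30 and 141. Line differences became 56, 261 and 1300 for NGI-1, 15, 283 and 1722 for acalabrutinib and 133, 396 and 1790 for copanlisib. For 24 h minus 3 h in TMD8 and HBL1 they became 3287 and 2327 for NGI-1, 3615 and 2101 for acalabrutinib and 3167 and 2855 for copanlisib. Direct comparisons gave NGI-1 against acalabrutinib 785 and 1424, NGI-1 against copanlisib 752 and 1940, acalabrutinib against copanlisib 486 and 478. Shared calls in HBL1 became 2898, 3454 and 3822 for NGI-1 with acalabrutinib, NGI-1 with copanlisib and acalabrutinib with copanlisib. Leaving out 1 library moved 128 of 260 counts. The lowest and highest were, at 3, 6 and 24 h, 42 to 89, 193 to 417 and 2992 to 3149 for NGI-1 in TMD8, 7 to 55, 43 to 164 and 1345 to 2203 in HBL1. They were 14 to 40, 231 to 428 and 2894 to 3685 for acalabrutinib in TMD8, 11 to 20, 233 to 531 and 1254 to 2113 in HBL1. For copanlisib they were 120 to 170, 955 to 1335 and 2688 to 3979 in TMD8, and 92 to 196, 635 to 1024 and 2576 to 3572 in HBL1. Line differences ranged over 0 to 2, 0 to 6 and 177 to 265 for NGI-1, 0 to 0, 12 to 25 and 345 to 474 for acalabrutinib, and 3 to 14, 39 to 68 and 331 to 495 for copanlisib. For 24 h minus 3 h the ranges in TMD8 and HBL1 were 950 to 1427 and 279 to 654 for NGI-1, 1176 to 1887 and 189 to 506 for acalabrutinib, and 664 to 1691 and 669 to 1174 for copanlisib. Direct comparisons ranged over 80 to 125 and 165 to 233 for NGI-1 against acalabrutinib, 103 to 129 and 280 to 387 for NGI-1 against copanlisib, and 32 to 54 and 2 to 23 for acalabrutinib against copanlisib. DMSO at 24 h against 3 h ranged over 2730 to 3703 and 4008 to 4376. Shared calls ranged over 2227 to 2736 and 661 to 1321 for NGI-1 with acalabrutinib, 2207 to 2836 and 1048 to 1797 for NGI-1 with copanlisib, and 2269 to 2971 and 1161 to 2082 for acalabrutinib with copanlisib. Of 396 list results the estimated correlation lost 116 calls, fry lost 46 and gained 22, the stricter filter lost 9 of 378, and RLE gained 1. The replicate block lost 2 and gained 8, and the block within line and time lost 2 and gained 16. Of 1584 list results without 1 library, 90 lost a call, 77 gained a call and 13 in HBL1 reversed direction, given here with the lowest and highest adjusted p. At 3 h with NGI-1 these were ATF4 and CHOP targets without DMSO replicate 1 (0.77, range 1.4e-10 to 0.93) and MHC class II without DMSO replicate 1 (0.0042) or NGI-1 replicate 2 (0.0041, range 0.0041 to 0.011). The p53 targets reversed without NGI-1 replicate 2 (0.048, range 0.021 to 0.24), and at 6 h MHC class II without DMSO replicate 2 (0.042, range 0.0051 to 0.19). With acalabrutinib at 3 h they were ATF4 and CHOP targets without acalabrutinib replicate 1 (0.00012) or DMSO replicate 2 (0.0018, range 2.2e-06 to 0.0018) and G1/S without acalabrutinib replicate 1 (0.034, range 0.0075 to 0.08). MHC class II reversed without acalabrutinib replicate 2 (0.0035) or DMSO replicate 1 (0.0044, range 0.0035 to 0.0077), and at 6 h G2/M without acalabrutinib replicate 1 (0.94) or DMSO replicate 2 (0.98, range 6.2e-06 to 0.98). With copanlisib at 3 h it was ATF4 and CHOP targets without copanlisib replicate 1 (0.018, range 5.5e-07 to 0.15). For named genes, 901 of 1368 results kept the same answer in every setting. DESeq2 gained 13 and lost 20 calls of 1346, no filter gained 34 and lost 32 of 1368, and RLE gained 1 and lost 15. Separate fits gained 11 and lost 63 of 1318, the stricter filter gained 4 and lost 14 of 1354. The replicate block gained 32 and lost 1, the block within line and time gained 64 and lost 0, and leaving out 1 library gained 8, lost 969 and reversed 0 of 5656.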

Other observations

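STAT3 and cytokine response genes fell early in TMD8 with all 3 compounds. Of 17 tested, NGI-1 lowered 7 and raised 0 at 6 h (8 lower over the list alone, median -0.65, camera adjusted p = 1.2e-15, 0.00048 with an estimated correlation). Already at 3 h the NGI-1 median was -0.28 (0 higher, 0 lower, 6 lower over the list alone, 4e-10, 0.0043 with an estimated correlation). Acalabrutinib lowered 5 and raised 0 at 3 h (7 lower over the list alone, median -0.33, 1.4e-18, 0.00029 with an estimated correlation). Copanlisib lowered 6 and raised 1 at 3 h (2 and 7 over the list alone, median -0.46, 2.7e-12, 0.0017 with an estimated correlation). In HBL1 at 3 h the median was -0.4 with acalabrutinib (0 higher, 1 lower, 5 lower over the list alone, 3.3e-06, 0.031 with an estimated correlation). There it was -0.49 with copanlisib (1 higher, 4 lower, 2 and 5 over the list alone, 0.00063, lost at adjusted p = 0.11) and -0.28 with NGI-1 (0 higher, 0 lower, 0.0058, lost at adjusted p = 0.21). Of 19 immediate early and ERK feedback genes, acalabrutinib lowered 5 in TMD8 at 3 h (0 higher, 13 lower over the list alone, median -0.83, 1.3e-27, 0.0018 with an estimated correlation). Copanlisib lowered 8 in TMD8 (0 higher, 14 lower over the list alone, median -1.02, 3.2e-23, 0.0043 with an estimated correlation). It lowered 7 in HBL1 (0 higher, 1 and 11 over the list alone, median -0.92, 2.6e-12, 0.038 with an estimated correlation). With acalabrutinib in HBL1 at 3 h 0 were higher and 1 lower (8 lower over the list alone, median -0.55, 4.8e-11, lost at adjusted p = 0.051 with an estimated correlation). With NGI-1 at 3 h 0 were higher and 2 lower in TMD8 (6 lower over the list alone, median -0.23, 8.7e-07, lost at adjusted p = 0.15 with an estimated correlation). In HBL1 0 were higher and 0 lower (median -0.1, mean 0.05, adjusted p = 0.095). BATF, an AP-1 factor gene that acts with IRF4, fell at 24 h by 1.3 ± 0.1 in TMD8 and 1.29 in HBL1 with NGI-1. It fell by 1.91 and 1.12 with acalabrutinib and by 1.26 and 1.2 with copanlisib. TFRC, the transferrin receptor gene, fell by 0.56 ± 0.07 and 1.09, 1.11 and 0.92, and 0.42 and 1.16. IL4R rose by 1.54 ± 0.1 and 0.54, 1.49 and 0.85, and 2.06 and 1.22. OAS1, an interferon-stimulated gene, rose by 1.38 ± 0.09 and 0.91 ± 0.09 with NGI-1 and 1.24 and 0.96 with copanlisib.

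Germinal centre genes were lower with NGI-1 than with each kinase inhibitor at 24 h. Of 11 tested, acalabrutinib raised 5 and lowered 0 in HBL1 at 24 h (median 0.39, camera adjusted p = 0.00029, 0.0048 with an estimated correlation). Copanlisib raised 6 and lowered 0 (median 0.63, 0.00087, 0.0097 with an estimated correlation). NGI-1 left the list lower than acalabrutinib in TMD8 (0 higher, 2 lower, 4 lower over the list alone, median -0.32, 0.00011, 0.003 with an estimated correlation). The list was also lower in HBL1 (0 higher, 3 lower, 6 lower over the list alone, median -0.47, 0.00016, 0.0032 with an estimated correlation). Against copanlisib it was lower in TMD8 (0 higher, 1 lower, 6 lower over the list alone, median -0.4, 0.00017, 0.0032 with an estimated correlation) and HBL1 (0 higher, 3 lower, 6 lower over the list alone, median -0.38, 1.8e-05, 0.0014 with an estimated correlation). Against DMSO in TMD8 at 24 h it was called higher by fry but not by camera with acalabrutinib (4 higher, 3 lower, adjusted p = 0.0091 and 0.49) and copanlisib (5 higher, 2 lower, 0.0052 and 0.27). With NGI-1 camera did not call it in TMD8 (4 higher, 3 lower, 4 and 4 over the list alone, median 0.06, mean -0.09, adjusted p = 0.83) or HBL1 (2 higher, 2 lower, median 0.3, adjusted p = 0.19), where fry called it higher (0.0058). RGS13 fell with NGI-1 in TMD8 by 1.53 ± 0.15 at 24 h (adjusted p = 1e-09). IGJ (JCHAIN), the joining chain of secreted immunoglobulin, rose 6.91-fold in TMD8 with NGI-1 (2.79 ± 0.27) and was not called in HBL1 (0.46, adjusted p = 0.085). Acalabrutinib raised it by 3.39 and 1.55 and copanlisib by 3.59 and 1.81. Of 12 plasma cell genes NGI-1 raised 7 and lowered 1 in TMD8 at 24 h (median 0.71, 0.026, lost at adjusted p = 0.38 with an estimated correlation). Acalabrutinib raised 4 and lowered 2 in HBL1 (7 and 2 over the list alone, median 0.41, 0.043), a call lost with an estimated correlation (adjusted p = 0.43) and without acalabrutinib replicate 2 (0.12) or DMSO replicate 1 (0.09). Of 21 lysosome and autophagy genes NGI-1 raised 11 and lowered 0 in TMD8 at 24 h (14 over the list alone, median 0.27, 0.00013, 0.0021 with an estimated correlation). In HBL1 3 rose and 3 fell (median 0.02, 0.83). CTSB, a cathepsin gene, rose in TMD8 by 0.85 ± 0.11, 0.91 and 0.79 with NGI-1, acalabrutinib and copanlisib.

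Of 12 MHC class II genes, 4 were higher and 0 lower with NGI-1 at 24 h in TMD8 (6 over the list alone, median 0.59, 0.0078, lost at adjusted p = 0.57 with an estimated correlation). In HBL1 2 were higher and 0 lower with a median of -0.07, a mean of 0.05 and an upward test (adjusted p = 0.55). Acalabrutinib raised 6 and 4 (0 lower, medians 0.62 and 0.39, 0.00059 and 0.00084, lost at adjusted p = 0.46 and adjusted p = 0.47 with an estimated correlation) in TMD8 and HBL1. Copanlisib raised 5 and 4 (0 lower, 7 over the list alone in TMD8, medians 0.63 and 0.5, 0.00082 and 0.00079, lost at adjusted p = 0.47 and adjusted p = 0.47 with an estimated correlation). HLA-DMB rose by 0.83 ± 0.14 and 0.82, 1.24 and 0.93, and 1.08 and 1.3 with NGI-1, acalabrutinib and copanlisib. Of 24 cholesterol synthesis genes copanlisib lowered 11 and raised 2 in TMD8 at 24 h (2 and 12 over the list alone, median -0.28, 0.00065, lost at adjusted p = 0.39 with an estimated correlation). It lowered 14 and raised 1 in HBL1 (1 and 15 over the list alone, median -0.33, 1.7e-05, lost at adjusted p = 0.25). With NGI-1 at 3 h in TMD8 that list was called higher (0 higher, 0 lower, 2 over the list alone, adjusted p = 0.0002, lost at adjusted p = 0.34 with an estimated correlation) although its median was 0.09 and its mean -0.01. Of 15 p53 targets copanlisib raised 3 and lowered 0 in HBL1 at 3 h (median 0.13, 0.00082), a call lost with an estimated correlation (adjusted p = 0.12) and without copanlisib replicate 2 (0.17) or DMSO replicate 1 (0.097). At 24 h camera did not call the list with any compound (adjusted p from 0.094 to 0.58). Fry called it higher with NGI-1 in TMD8 (4 higher, 0 lower, 3 higher over the list alone, 0.049) and copanlisib in HBL1 (5 higher, 1 lower, 0.034).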
